A study of Mus musculus with 6 samples.

How the data were processed

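Polyadenylated RNA was profiled in 6 libraries of mouse 2H11 cells, a line that the labels describe as endothelial, from an axillary lymph node of the C3H/HeJ strain. The cells were starved and then kept for 48 h with BMP4 (3 libraries) or with BMP4 plus palovarotene (3 libraries). Libraries were strand-specific and were read from both ends on an Illumina instrument, per the labels' protocols. The submitters' processing notes name FastQC, cutadapt, HISAT2 and StringTie, without versions, and the genome build GRCm38. The role and settings of each tool are not given in the sources used here.

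The values are FPKM, fragments relative to transcript length and to the total of mapped fragments, computed by the authors and deposited in a table of genes and a table of transcripts, per the file headers. Every row in both tables carried the type protein-coding. The lower bound of the authors' selection was read from the values: the higher of the 2 group means was never below 0.5004 FPKM over 11773 listed genes, nor below 0.5001 over 22330 listed transcripts. Genes under that level in both groups are not analysed here, so that silent genes cannot be told from genes near the bound. Each table held 1 line without values. Group and replicate of each column were taken from the sample descriptions, which match the column names; no column of values per sample was left unused. Gene coordinates are those of the tables, on GRCm38. Of the gene identifiers, 10300 had the same version in GENCODE vM21, and all 10300 had the same start and end there.

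FPKM values hold no read counts. Steps of single fragments were searched for in low transcript values of genes with 1 listed transcript; the best step fitted no better (mean cosine of 0.077 to 0.0927) than it did in the same values jittered at random (0.0957 to 0.137), so the depth of the libraries is unknown and no counting interval is given. The listed genes summed to between 244119 and 251290 FPKM per library. The gene FPKM was a median of 0.826 times the sum of the listed transcripts' FPKM and was at or below that sum in 88.6% of values, within a tolerance of 0.0001, so gene and transcript values are not interchangeable. Whether reads were assigned by strand is not given in the sources used here, so values of overlapping genes are uncertain. Between 11 and 17 genes were listed at 0 in a library.

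Expression was compared with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a trend of the variance on the mean level and Benjamini-Hochberg adjustment. Rows with a mean of at least 0.5 FPKM over the 6 libraries were tested: 11584 genes and 21101 transcripts. A row was called changed at an adjusted p below 0.05. Log2 fold changes are on the log2(FPKM + 1) scale, as BMP4 + palovarotene minus BMP4, and understate the change of genes of low level; ratios of mean FPKM are given beside some. The authors' scaling was kept. No replicate block was used, since the labels do not say that a replicate number marks a shared culture or day.

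Gene lists were tested with camera at its preset inter-gene correlation of 0.01, adjusted over the 26 lists with at least 3 tested members, with camera at an estimated correlation and with fry beside it. There were 27 lists: retinoic acid targets; retinoid receptors and binding proteins; 3-prime Hox genes; BMP-SMAD targets; BMP ligands, receptors and SMADs; osteoblast, chondrocyte, endothelial, mesenchymal transition, smooth muscle, leukocyte and epithelial genes; matrix genes; matrix proteases and inhibitors; TGF-beta targets; Notch; Wnt; S-phase; mitosis; p53 targets and CDK inhibitors; interferon response; inflammatory and NF-kB genes; cholesterol synthesis; ER stress; hypoxia and glycolysis; immediate-early and heat-shock genes; and mitochondrially encoded genes. Where a symbol had more than 1 row, the row with the higher mean was used.

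The lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The rule takes the 10 higher and the 10 lower genes with the largest absolute log2 fold change among called genes whose groups do not overlap and whose mean is at least 1 FPKM; 17 fixed genes, of which 12 were tested; and up to 4 members of each list with the smallest p. Other genes of a list are named as examples of it and were chosen after their values were seen. The alternatives were a pseudocount of 0.1, no filter, a filter at a mean of 5 FPKM, quantile normalization, median-ratio scaling, limma without the trend, a replicate block, and each library left out in turn. Total scaling without mitochondrial genes was added after the data were seen. A count test was planned only for the case that the values were counts and was not run.

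The test was tried on simulated values made from the means and residual spread of the real rows, with 67 rows changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold in each table, all at a mean of log2(FPKM + 1) above 2. In the gene table (11584 genes) it recovered 85.1% of changes of 1.5-fold, 97.0% of 2-fold and 100.0% of 4-fold, and 7.39% of its calls were false. In the transcript table (21101 transcripts) it recovered 34.3%, 64.2% and 81.8% of changes of those sizes, and 6.25% of its calls were false. Camera at the preset correlation called 5 of 5 simulated lists of 15 genes raised by 0.5 on the log2 scale and 0 of 20 unchanged lists of that size, with genes simulated as independent. Far fewer rows were changed in the simulation than were called in the real data, 4976 of 11584 genes and 2724 of 21101 transcripts. The shares recovered, the false shares and the list calls therefore do not carry over to the real calls.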

Results

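The transcriptome of 2H11 cells, a mouse line labelled as endothelial, was measured after 48 h with bone morphogenetic protein 4 (BMP4) alone or with BMP4 and palovarotene. BMP4 is a secreted ligand that drives bone and cartilage formation through SMAD signalling. Palovarotene is a synthetic retinoid that activates the retinoic acid receptor gamma. The comparison addresses what the retinoid changes in cells exposed to BMP4. There was no group without BMP4, so what BMP4 itself changed was not measured. Each group held 3 libraries, and the labels do not say whether these came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Pearson's r of log2(FPKM + 1) across the listed genes was 0.989 to 0.992 between BMP4 libraries, 0.993 to 0.994 between BMP4 + palovarotene libraries and 0.956 to 0.960 between groups, where genes are not independent replicates.

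Palovarotene changed a large part of the transcriptome, and genes of retinoid metabolism and signalling were among those that rose most. Cyp26b1, which encodes an enzyme that degrades retinoic acid, rose from 0.303 ± 0.0231 to 107 ± 4.33 FPKM (SD, n = 3), a log2 fold change of 6.37 with an SE of 0.0490 (limma adjusted p = 5.3e-09). It was followed by Alpl, the tissue-nonspecific alkaline phosphatase of mineralizing cells (5.69), by Tgm5, a transglutaminase (5.15), and by Dhrs3, which reduces retinaldehyde (4.89). The other genes of the 10 with the largest rise were Stra6, Ogn, Rarb, Sprr1a, Rarres2 and Hic1, with log2 fold changes between 3.15 and 3.90. This order holds on the log2(FPKM + 1) scale. By the ratio of mean FPKM, Stra6 (194) and Rarb (167) lay above Tgm5 (146) and Dhrs3 (33). The largest fall was that of Sfrp2, which encodes a secreted Wnt modulator, from 30.8 ± 1.5 to 0.282 ± 0.0549 FPKM (SD, n = 3), a log2 fold change of -4.63 with an SE of 0.0601 (adjusted p = 6.24e-08). Dpt, a matrix protein gene, followed at -3.96 and Cbr2, a carbonyl reductase gene, at -3.60. Mgp, an inhibitor of calcification, fell by 3.31, and Krt14, Aldh1a3, Grem1, Inhbb, Clec3b and Bglap2 fell by between 2.88 and 3.25. Of 11584 genes tested, 4976 changed (43.0%), 2217 higher and 2759 lower with palovarotene. Most changes were small: the median absolute log2 fold change of the changed genes was 0.36, and 432 genes changed at least 2-fold, 240 higher and 192 lower. The values of the groups did not overlap in 6359 genes (54.9%), where chance alone gives 10%. With a pseudocount of 0.1 the number of genes changed at least 2-fold was 739.

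**Figure D1:**
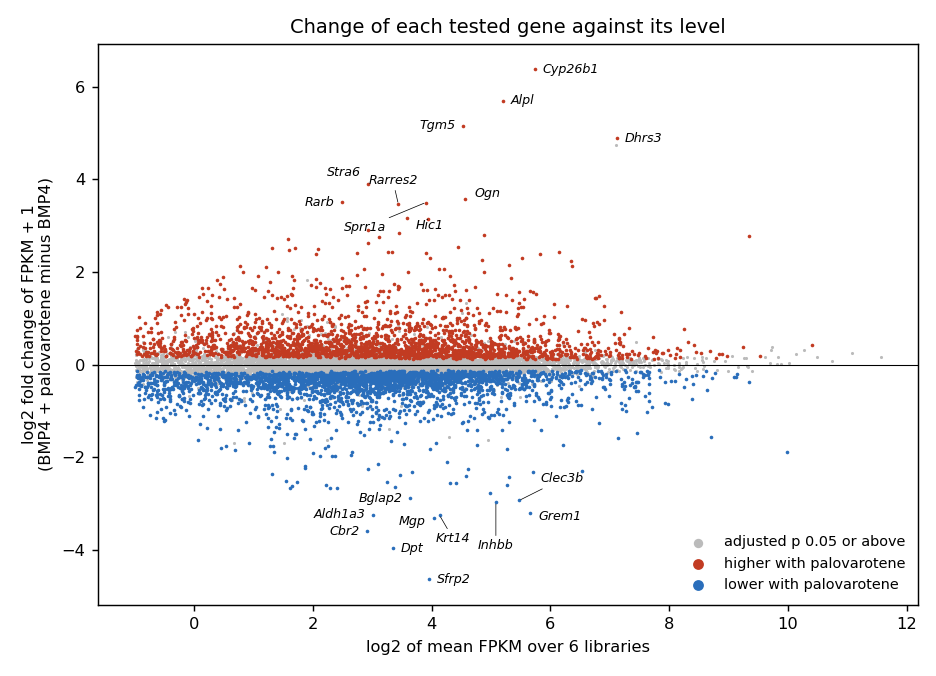
Each point is 1 tested gene, with the log2 of its mean FPKM over the 6 libraries on the x axis and its log2 fold change on the log2(FPKM + 1) scale on the y axis, red where higher and blue where lower with palovarotene past the limma test. The 10 genes with the largest rise and the 10 with the largest fall are named; Cyp26b1 lies at 6.37 and Sfrp2 at -4.63.

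Among the 20 retinoic acid targets fixed in advance, 13 were tested, of which 11 rose and 2 fell, with the same counts adjusted over the list alone. Cyp26b1 (chromosome 6, 84571414 to 84593908, GRCm38) had a mean FPKM 352 times that of BMP4 alone. Dhrs3 (chromosome 4, 144892827 to 144928209) rose from 8.2 ± 0.508 to 271 ± 7.07 FPKM (SD, n = 3). Rarb (chromosome 14, 16430839 to 16819156), a retinoic acid receptor gene that is itself a target of these receptors, rose from 0.0668 ± 0.0088 to 11.1 ± 0.331 FPKM, and Stra6, the gene of a retinol transporter, from 0.0779 ± 0.0307 to 15.1 ± 0.548. The 2 members that fell were Zfp703 (log2 fold change -0.53) and Rarres1 (-0.46). Cyp26a1, another retinoic acid hydroxylase gene, lay under the level required for the test: it was at 0.0437 to 0.13 FPKM in the BMP4 libraries and at 0.51 to 0.946 in those with palovarotene. The list's median log2 fold change was 2.14 and camera placed it above the other genes (adjusted p = 2.48e-08). That call did not hold with an estimated correlation, here 0.0454 (camera unadjusted p = 0.00646, adjusted p = 0.168).

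Of the retinoid receptors and binding proteins, 9 genes were tested, with 3 higher and 5 lower over all genes and 4 higher and 5 lower adjusted over the list alone. Of the 5 lower, Rdh10 (log2 fold change -0.14, limma adjusted p = 0.0477) lost its call whichever library was left out. Rarg, the receptor that palovarotene activates, rose from 55.9 ± 3.65 to 84.9 ± 2.11 FPKM (SD, n = 3), whereas Rara fell from 12.8 ± 1.2 to 9.83 ± 0.253. Aldh1a3, which encodes an enzyme that makes retinoic acid, fell from 15.3 ± 0.833 to 0.722 ± 0.0788 FPKM, and Nr2f1, an orphan nuclear receptor gene, rose by a log2 fold change of 2.05. The list as a whole did not pass camera (adjusted p = 0.891).

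The 3-prime Hox genes, which lie at the end of each Hox cluster that responds first to retinoic acid in the embryo, rose in 9 of 10 tested members, with the same count adjusted over the list alone. Hoxa5 (chromosome 6, 52201754 to 52204587) rose from 12.1 ± 0.434 to 40.6 ± 1.04 FPKM (SD, n = 3), Hoxa4 rose by a log2 fold change of 1.32 and Hoxb3 by 0.99. Hoxb5 was at 3.77 ± 0.151 and 3.41 ± 0.532 FPKM and did not pass the test (adjusted p = 0.345). Hoxa3, Hoxa4, Hoxa5 and Hoxc5 overlap another listed gene on the same strand, so their separate values are uncertain. Camera called the list (adjusted p = 9.84e-06), but not with an estimated correlation (adjusted p = 0.204).

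**Figure D2:**
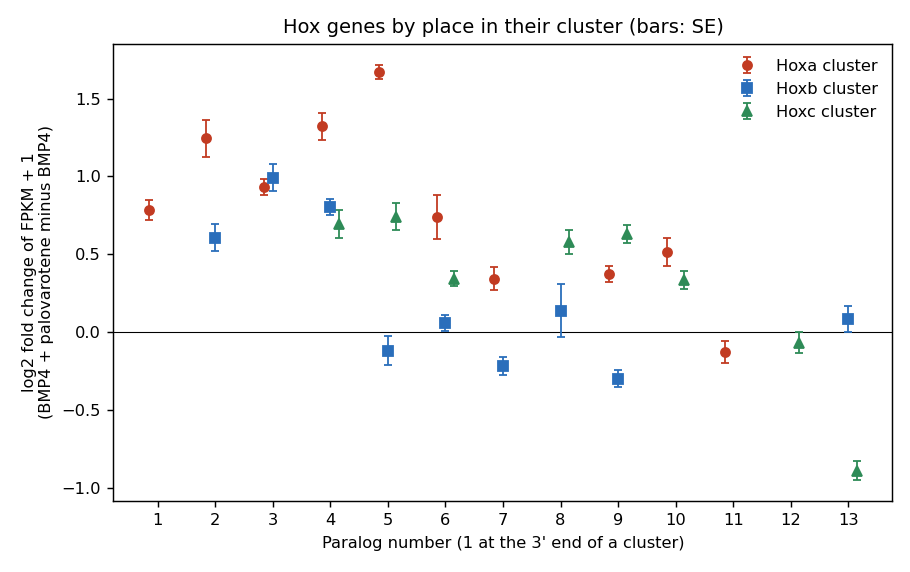
Log2 fold change on the log2(FPKM + 1) scale (y axis) of the 27 tested Hox genes against their paralog number (x axis), for the Hoxa (red circles), Hoxb (blue squares) and Hoxc (green triangles) clusters, with error bars of 1 SE. Hoxa5 lies highest at 1.67, and Hoxc13, chosen after its value was seen, lies lowest at -0.89.

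Genes of the osteoblast moved in both directions. Of 24 osteoblast genes, 15 were tested, with 7 higher and 4 lower over all genes and 7 higher and 5 lower adjusted over the list alone. Alpl (chromosome 4, 137741733 to 137796384) rose from 0.432 ± 0.0285 to 73.0 ± 1.66 FPKM (SD, n = 3; log2 fold change 5.69, SE 0.0454, adjusted p = 5.3e-09). Ogn, the gene of the proteoglycan osteoglycin, rose by 3.58, Pth1r, the parathyroid hormone receptor gene, by 1.27 and Spp1, osteopontin, by 0.96. Col1a1, the main collagen gene of bone, rose from 523 ± 32.9 to 684 ± 25.2 FPKM (log2 fold change 0.39, adjusted p = 0.00183). Against these, the osteocalcin genes fell: Bglap (chromosome 3) from 10.5 ± 1.69 to 1.98 ± 0.439 FPKM and Bglap2 (chromosome 3, 88377736 to 88378699) from 22.6 ± 1.46 to 2.22 ± 0.396. Bglap, Bglap2 and Bglap3 are near-identical neighbours whose reads can be split among them; their summed FPKM fell from 36.5 ± 3.26 to 4.56 ± 0.832. Runx2, the transcription factor gene that starts osteoblast differentiation, fell from 6.56 ± 0.0587 to 3.65 ± 0.169 FPKM (log2 fold change -0.70, adjusted p = 5.92e-05). Ank, a pyrophosphate transporter gene, fell by 1.41. Sp7, a further fixed gene, is not analysed here. The list did not pass camera (adjusted p = 0.199).

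**Figure D3:**
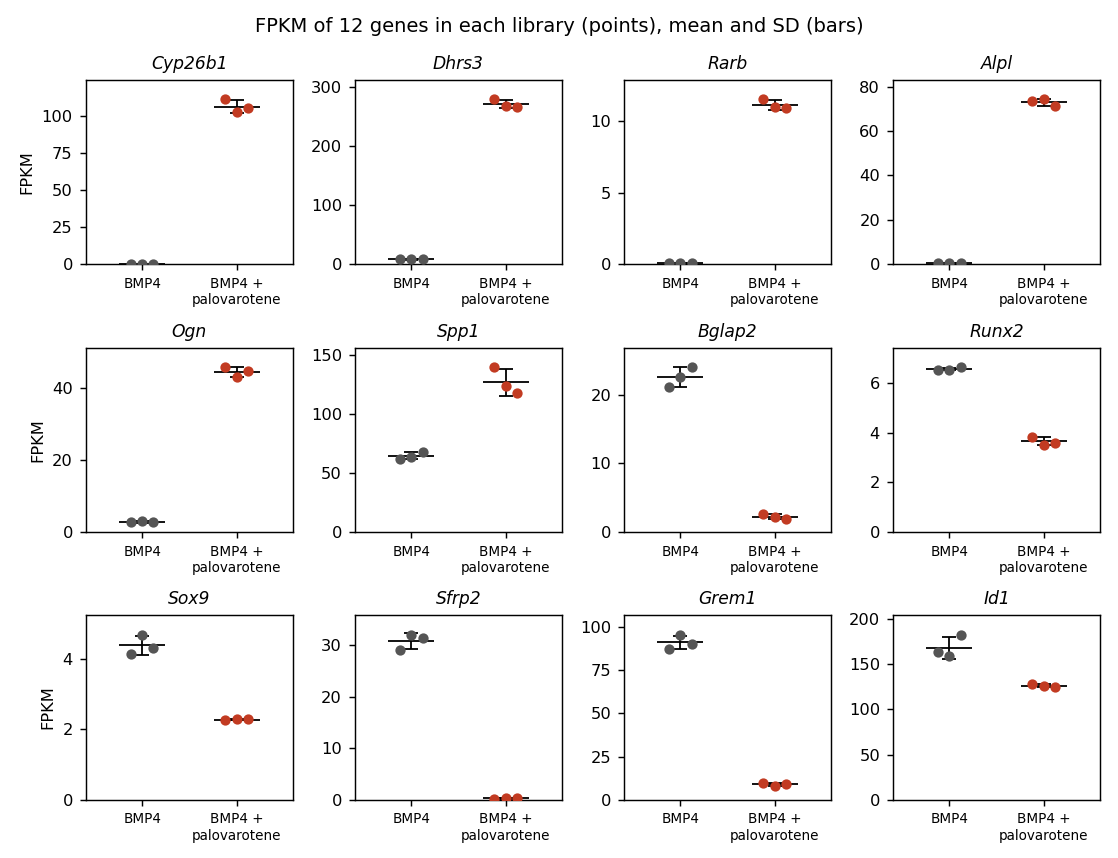
FPKM on the y axis of 12 genes in each of the 3 BMP4 libraries (grey) and the 3 BMP4 + palovarotene libraries (red), with horizontal bars at the mean and error bars of 1 SD; each panel starts at 0. Alpl rises from 0.432 to 73.0 FPKM while Bglap2 falls from 22.6 to 2.22 and Runx2 from 6.56 to 3.65.

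All 4 tested chondrocyte genes fell, by the test over all genes and adjusted over the list alone, among them Sox9, the main regulator gene of cartilage, from 4.38 ± 0.270 to 2.28 ± 0.0103 FPKM (SD, n = 3) and Col11a1 from 3.29 ± 0.495 to 1.2 ± 0.0722. Matn3 fell from 0.941 ± 0.162 to 0.230 ± 0.0664 FPKM and Col9a3 from 0.920 ± 0.251 to 0.326 ± 0.068. Both lay near the level required for the test, and Matn3 was not tested without BMP4 replicate 1. Camera called the list lower (adjusted p = 0.0147), but not with an estimated correlation (adjusted p = 0.204), and the list holds 4 of 17 members fixed. Col10a1, a collagen gene of hypertrophic cartilage, lay under the level required for the test, at 0.679 to 0.792 FPKM with BMP4 and 0.0570 to 0.0659 with palovarotene.

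Direct targets of BMP-SMAD signalling did not move one way. Of 17 tested, 5 rose and 7 fell, with the same counts adjusted over the list alone, and the list did not pass camera (adjusted p = 0.715). The largest changes were falls of genes of secreted antagonists: Grem1, gremlin 1, fell from 91.2 ± 3.96 to 9.06 ± 0.832 FPKM (SD, n = 3) and Fst, follistatin, from 21.7 ± 1.00 to 3.59 ± 0.354. Smad6, the gene of an inhibitory SMAD, rose from 46.9 ± 1.92 to 79.5 ± 1.59 FPKM. The Id genes, among the most direct BMP targets, were split, with Id1 lower (log2 fold change -0.41, SE 0.0568, adjusted p = 0.00133), Id4 lower (-0.59), Id2 higher (0.99) and Id3 higher (0.33). Among the BMP ligands, receptors and SMADs, 1 of 13 tested genes rose (2 without BMP4 replicate 2) and 3 fell, with the same counts adjusted over the list alone. Smad1 rose from 7.71 ± 0.120 to 15.2 ± 0.247 FPKM, and Bmp4 itself fell from 5.34 ± 0.114 to 1.74 ± 0.148. Acvr1, a BMP receptor gene, fell by 0.26 and Smad5 by 0.38. That list did not pass camera either (adjusted p = 0.747).

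Markers of cell types were mixed. Of the 24 endothelial markers, 7 were tested, with 1 higher and 3 lower, as also adjusted over the list alone. Without BMP4 replicate 1, 2 or 3 the number higher was 2 in each case. The members tested were then 7, 8 and 7 and not the same ones, so these counts do not compare like with like. Flt1, a receptor gene for vascular endothelial growth factor, fell from 3.93 ± 0.0792 to 1.27 ± 0.0730 FPKM (SD, n = 3), Vwf from 1.17 ± 0.126 to 0.0258 ± 0.00298 and Tek from 1.86 ± 0.130 to 0.697 ± 0.128, while Flt4, the receptor gene of lymphatic endothelium, rose from 1.06 ± 0.134 to 3.04 ± 0.225. Without BMP4 replicate 1 or replicate 3, Vwf was not tested, its mean being too low. Sox7 and Fli1 lay under the level required for the test: Sox7 was at 0 to 0.0233 FPKM in the BMP4 libraries and at 0.889 to 1.09 in those with palovarotene, and Fli1 at 0.163 to 0.264 and at 0.388 to 0.741. Pecam1, Cdh5 and Kdr are not analysed here. The list did not pass camera (adjusted p = 0.202). Of 17 mesenchymal transition genes, 4 rose and 11 fell, as also adjusted over the list alone, without a call by camera (adjusted p = 0.169). Among genes with a mean of at least 5 FPKM camera called this list lower (adjusted p = 0.0373), and over the settings tried its adjusted p lay between 0.0373 and 0.187. With an estimated correlation over all tested genes the adjusted p was 0.366. S100a4 fell from 1602 ± 101 to 431 ± 8.26 FPKM, Snai2 from 93.3 ± 6.82 to 42.5 ± 1.40 and Vim by a log2 fold change of 0.78, whereas Fap rose by 2.50 and Pdgfra from 9.25 ± 0.540 to 28.0 ± 0.579 FPKM. Smooth muscle markers fell in 7 of 8 tested members and Des rose, with the same counts adjusted over the list alone. The call of Tpm2 (log2 fold change -0.16, limma adjusted p = 0.0232) was lost without BMP4 replicate 3 or any BMP4 + palovarotene replicate. Its transcripts moved in opposite directions, Tpm2-203 by 0.41 and Tpm2-202 by -0.62. Acta2, smooth muscle actin, fell from 159 ± 2.52 to 66.3 ± 1.92 FPKM, and Tagln and Lmod1 fell by 0.69 and 0.73. Camera called that list lower (adjusted p = 0.0147), but not with an estimated correlation (adjusted p = 0.204). Of 3 leukocyte markers tested, Cd68 and Cd14 fell, as also adjusted over the list alone (list adjusted p = 0.177), and the only epithelial marker tested, Krt19, rose from 9.98 ± 1.13 to 32.0 ± 0.582 FPKM.

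Genes of the matrix and of its enzymes moved in both directions. Of 27 matrix genes, 9 rose and 15 fell, as also adjusted over the list alone (camera adjusted p = 0.175). Loxl2, a collagen crosslinking enzyme gene, rose from 28.0 ± 2.92 to 134 ± 4.98 FPKM (SD, n = 3) and Nid1 rose by a log2 fold change of 1.45, while Lox fell from 261 ± 26.5 to 92.2 ± 4.18, Thbs1 from 154 ± 17.1 to 30.3 ± 1.6, and the collagen VI genes Col6a1, Col6a2 and Col6a3 by between 0.97 and 1.71. Among the matrix proteases and inhibitors, 5 rose and 10 fell of 17 tested, as also adjusted over the list alone (camera adjusted p = 0.239). Mmp3, stromelysin 1, rose from 14.8 ± 1.42 to 76.6 ± 1.92 FPKM, and Adamts5 fell from 21.7 ± 0.440 to 8.82 ± 0.397.

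Among signalling pathways, most of the changed Wnt genes fell, and the other lists were split. Of 14 Wnt genes, 1 rose and 9 fell over all genes, and 2 rose and 9 fell adjusted over the list alone; without BMP4 replicate 2, 2 rose over all genes. Besides Sfrp2, the members that fell included Nkd2, a feedback inhibitor gene (log2 fold change -1.39), and the ligand genes Wnt4 (-1.10) and Wnt5a (-1.08). Axin2, the usual readout of canonical signalling, fell from 0.866 ± 0.0653 to 0.559 ± 0.111 FPKM (SD, n = 3; log2 fold change -0.26), a call lost without BMP4 replicate 1 (-0.25) or BMP4 replicate 2 (-0.24), and Dkk3 rose by 0.75. Camera called the list lower (adjusted p = 0.0147), but neither with an estimated correlation (adjusted p = 0.204) nor among genes with a mean of at least 5 FPKM (adjusted p = 0.149). Over the settings tried, its adjusted p lay between 0.00958 and 0.149. Of 13 TGF-beta target, ligand and receptor genes, 6 rose and 4 fell, as also adjusted over the list alone (camera adjusted p = 0.202), led by Pmepa1, a feedback inhibitor gene, which rose from 24.5 ± 0.0217 to 75.7 ± 1.29 FPKM, and Tgfb2, which rose by 0.99. Without BMP4 + palovarotene replicate 1 or replicate 3, 5 of them rose and 2 fell. Of 7 Notch genes, 2 rose and 4 fell over all genes, and 3 rose and 4 fell adjusted over the list alone (camera adjusted p = 0.690). Jag1, a ligand gene, fell by 1.05 and Notch3 rose by 0.60. Notch4, under the level required for the test, was at 0.0279 to 0.0799 FPKM with BMP4 and 0.371 to 0.819 with palovarotene.

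Of 17 S-phase genes, 6 fell, as also adjusted over the list alone; Mcm4, a subunit gene of the replicative helicase, fell from 157 ± 7.58 to 98 ± 2.13 FPKM (SD, n = 3), and the next largest fall among the 6 was that of Pcna (log2 fold change -0.21). The number that fell was 3 without BMP4 replicate 1 and 2 without BMP4 replicate 3, BMP4 + palovarotene replicate 2 or replicate 3. Of the 6, the calls of Mcm4 and Pcna held whichever library was left out, those of Mcm2 (adjusted p = 0.0401) and Ccne1 (adjusted p = 0.0404) held only without BMP4 replicate 2, the call of Slbp was lost whichever library was left out (-0.15 to -0.12), and that of Gins2 without BMP4 replicate 3 (-0.17), BMP4 + palovarotene replicate 2 (-0.19) or replicate 3 (-0.15). Of 20 mitosis genes, 5 rose and 1 fell over all genes, and 3 rose and 1 fell adjusted over the list alone; the number that rose was 3 without BMP4 replicate 2, BMP4 replicate 3 or BMP4 + palovarotene replicate 2, 1 without BMP4 + palovarotene replicate 1 and 2 without BMP4 + palovarotene replicate 3. Their changes were small, with Cenpa at 0.30 and Bub1 at 0.22. The call of Cenpa was lost without BMP4 replicate 3 (log2 fold change 0.24) and without BMP4 + palovarotene replicate 1 (0.25), and over the settings tried its adjusted p lay between 0.00793 and 0.0669. That of Ube2c was lost without BMP4 + palovarotene replicate 1 (0.22) or replicate 3 (0.19), and those of Aurkb and Birc5 were each lost in 5 of the 6 ways to leave out 1 library. Neither list passed camera (adjusted p = 0.175 for each). Of all tested genes 43.0% changed, a larger share than in either list. Of 19 p53 targets and CDK inhibitors, 3 rose and 13 fell over all genes, and 4 rose and 13 fell adjusted over the list alone (camera adjusted p = 0.129). Cdkn1a, the p21 gene, fell from 309 ± 19.7 to 240 ± 5.49 FPKM and Pmaip1 from 8.50 ± 0.320 to 5.93 ± 0.264.

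Genes of cholesterol synthesis rose in 11 of 20 tested members and fell in none, with the same counts adjusted over the list alone. Mvd rose from 34.8 ± 3.49 to 64.8 ± 3.94 FPKM (SD, n = 3) and Nsdhl by a log2 fold change of 0.77. Camera called the list higher (adjusted p = 1.94e-04), but not with an estimated correlation (adjusted p = 0.366). Of 24 interferon-response genes, 6 rose and 6 fell over all genes, and 6 rose and 7 fell adjusted over the list alone; the mean log2 fold change was 0.0421, the median -0.0856 and the direction by camera lower (adjusted p = 0.747). Oasl1 rose from 2.34 ± 1.37 to 16.8 ± 6.15 FPKM and Ifit3 fell from 6.06 ± 0.455 to 3.61 ± 0.367. Of 17 inflammatory and NF-kB genes, 6 rose and 5 fell over all genes, and 6 rose and 6 fell adjusted over the list alone; their mean was 0.0679, their median -0.0026 and the direction by camera higher (adjusted p = 0.690). Tnfaip3, an inhibitor gene of NF-kB signalling, rose from 0.505 ± 0.212 to 3.57 ± 0.619 FPKM, and Ccl7, a chemokine gene, fell from 50.6 ± 3.12 to 25.7 ± 1.99. Of 18 genes of ER stress and the amino acid response, 7 rose and 2 fell, as also adjusted over the list alone (camera adjusted p = 0.175), where Pdia4 rose by a log2 fold change of 0.34 and Ddit3 fell by 0.39; 4 rose without BMP4 replicate 2, BMP4 + palovarotene replicate 1 or replicate 3, and without the last of these 1 fell. Of 15 hypoxia and glycolysis genes, 7 rose and 2 fell (1 without BMP4 + palovarotene replicate 3), as also adjusted over the list alone (camera adjusted p = 0.169); Ndrg1 fell from 53.3 ± 2.16 to 19.4 ± 0.374 FPKM and Vegfa rose from 8.99 ± 0.827 to 15.4 ± 0.761.

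Of the lists, 2 bear on RNA quality and handling. Of 12 immediate-early and heat-shock genes, 2 rose and 3 fell, as also adjusted over the list alone (camera adjusted p = 0.690): Dusp1 and Jun rose, and Nr4a1 and the near-identical Hspa1a and Hspa1b fell; without BMP4 replicate 1, 5 fell. Of the 13 mitochondrially encoded genes, 0 passed limma's test, adjusted over all genes or over the list alone, and 1, mt-Co1, passed at an unadjusted threshold of 0.05. The count of 0 depends on single libraries: without BMP4 replicate 2, 5 were higher past limma's test, mt-Nd4l, mt-Nd5, mt-Co1, mt-Atp8 and mt-Cytb, with adjusted p between 0.0161 and 0.0329, and without BMP4 replicate 1, mt-Nd6 was lower (adjusted p = 0.0379). The list did not pass camera (adjusted p = 0.123), but was called higher without BMP4 replicate 2 (adjusted p = 0.0145). With all libraries and an estimated correlation the adjusted p was 0.745, and over the settings tried with the preset correlation it lay between 0.0145 and 0.309. Their share of the listed FPKM was 4.57% to 6.10% in the BMP4 libraries and 6.01% to 6.38% in those with palovarotene. Of the 26 lists tested, 6 passed camera at its preset correlation of 0.01. As many passed in 1 other split of the libraries, which mixed the treatments, so that number alone does not set the treatment apart. With an estimated correlation 0 passed, and 5 had an unadjusted p below 0.05. The estimate was below the preset for the chondrocyte (-0.0131), smooth muscle (-0.0696) and Wnt (-0.0168) lists, which lost their calls all the same. A larger correlation was therefore not what ended those calls. With an estimated correlation camera also uses the few residual degrees of freedom of the fit, which by itself raises its p-values. A call lost at that setting therefore does not show that the genes of a list are correlated. By fry, 20 lists moved on balance one way and 25 changed in either direction, which does not compare a list with other genes.

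**Figure D4:**
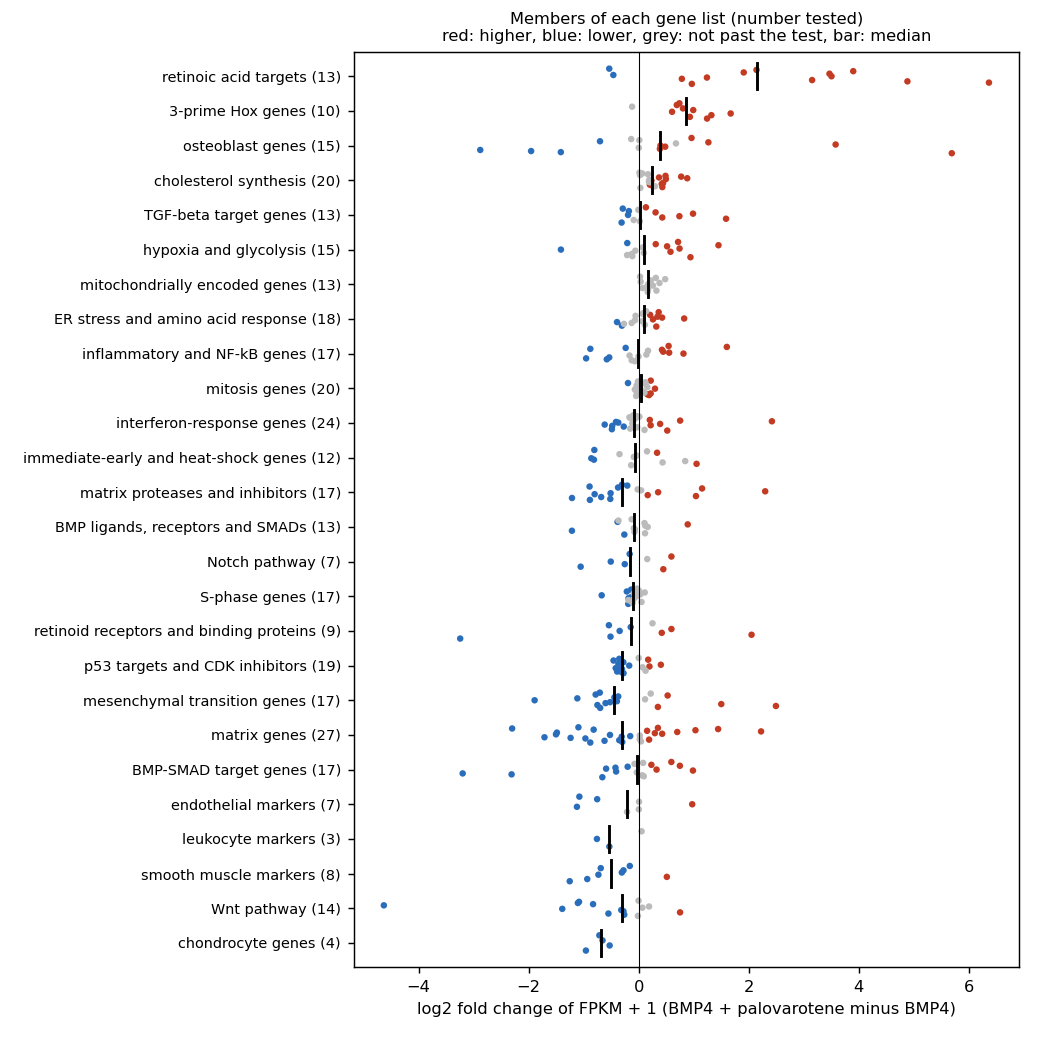
Each point is 1 tested member of a gene list, with its log2 fold change on the log2(FPKM + 1) scale on the x axis and the lists, ordered by mean log2 fold change, on the y axis; red members are higher and blue members lower past the limma test, grey members did not pass, and black bars are medians. The retinoic acid targets have a median of 2.14, and the osteoblast genes reach from -2.88 for Bglap2 to 5.69 for Alpl.

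Of 21101 transcripts tested, 2724 changed, 1370 higher and 1354 lower, and 648 of them at least 2-fold. They belonged to 2456 genes, of which 2300 changed in the gene test. In 19 genes, transcripts changed in both directions. In Pcyt1b, the gene of a phosphocholine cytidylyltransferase, transcript Pcyt1b-201 rose from 0.774 ± 0.229 to 6.50 ± 0.297 FPKM (SD, n = 3) while Pcyt1b-202 fell from 6.27 ± 0.534 to 0.0368 ± 0.0637. In Cacnb3, a calcium channel subunit gene, Cacnb3-201 rose from 34.7 ± 7.67 to 84.5 ± 7.64 FPKM while Cacnb3-202 fell from 35.7 ± 5.65 to 16.9 ± 3.07. These 2 genes were chosen after their values were seen, and the split of reads among transcripts of a gene is an estimate. The number of transcripts changed was 1722 without BMP4 replicate 3 and 1468, 1610 and 1505 without BMP4 + palovarotene replicates 1, 2 and 3.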

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

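Of the alternatives, total scaling without mitochondrial genes was chosen only after the data were seen; the count-based test was not run, because the values are FPKM. Over the settings, of the values for the 120 named genes 1626 had the direction and side of the threshold of the reported ones. Of the rest, 18 lost the call, 3 gained it and 2 were reversed. For the values of list means these numbers were 349, 1, 3 and 8. Of the counts of genes, transcripts and lists called, 74 were within 1.5 times the reported count and 12 were not. Quantile normalization, median-ratio scaling, total scaling without mitochondrial genes, no filter and limma without the trend moved none of these counts by more than 1.5 times. Counts within single lists are not among them, and were recomputed only with the block and with 1 library left out. Median-ratio scaling ended the call of Slbp (log2 fold change -0.10), and ended no other call of those 120 genes or of a list; the share of changed genes that were higher was 44.6% as reported and 50.9% there. With a pseudocount of 0.1, 739 genes changed at least 2-fold against 432, since the log2 scale then shrinks low values less. With a filter at a mean of 5 FPKM, 7378 genes were tested and 3111 changed; the genes higher with palovarotene numbered 1419, the genes lower with palovarotene 1692 and the genes changed at least 2-fold 259; 3110 of the 3111 were also called with the reported filter. The chondrocyte, endothelial and leukocyte lists then had too few members for a value. At that filter the direction by camera turned, without a call before or after, for the retinoid receptors and binding proteins (mean log2 fold change -0.12), the BMP ligands, receptors and SMADs (0.0089), the Notch pathway (0.0366), interferon-response genes (0.33) and inflammatory and NF-kB genes (-0.10), with fewer members tested. Of the 26 lists tested, camera called 6 with the preset correlation and 0 with an estimated correlation, and fry, which does not compare a list with other genes, called 20.

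With the replicate number as a block, 715 transcripts changed against 2724, and 3844 genes. The block ended the calls of Pcna, Gins2, Slbp and Pttg1. It gave a call for the list mitochondrially encoded genes by camera at the preset correlation (adjusted p below 0.05). Without the block that list had an adjusted p of 0.123 by the same test, and 0.745 with an estimated correlation. The block changed no other call of those 120 genes or of a list as a whole. Of 241 called members of the lists, 31 lost the call with the block, 27 of them outside the 120 genes and Mcm2, Ccne1, Aurkb and Birc5 among these. The counts it moved by over 1.5 times were those of S-phase genes lower (1 against 6), mitosis genes higher (3 against 5) and lower (0 against 1), TGF-beta genes lower (2 against 4), p53 targets and CDK inhibitors higher (1 against 3) and immediate-early and heat-shock genes higher (4 against 2). The numbers did not pair the libraries: residuals of libraries with the same number correlated at -0.064, -0.136 and -0.0207 across genes, and for none was its own number the highest. Leaving out 1 library at a time gave 1468 to 2341 changed transcripts and 3826 to 4798 changed genes, with fewer samples in the fit. The direction by camera, which ranks a list against the other genes, turned without a call while the mean log2 fold change of the list stayed negative, for the retinoid receptors and binding proteins without BMP4 replicate 1 (range of means -0.18 to -0.14), for the mean log2 fold change of the list BMP ligands, receptors and SMADs without BMP4 replicate 2 (-0.11 to -0.0716) and for the endothelial markers without BMP4 replicate 3 (-0.32 to -0.014). The log2 fold change of Lyz2, not called, changed sign without BMP4 replicate 1 or BMP4 + palovarotene replicate 3 (-0.0893 to 0.16); the cause was not tested. Depth is unknown, so the counting error of low values was not separated from the spread between libraries.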

Other observations

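The 4 gene lists of the first paragraphs, the tests of the osteoblast genes, the test of GC content, the search for genes at 0 in single libraries and the choice of Hox paralogs and neighbouring genes as patterns came only after results were seen. Genes of small leucine-rich proteoglycans, which bind collagen in the matrix, fell in 8 of 9 tested members. Fmod, fibromodulin, fell from 34.3 ± 2.22 to 5.06 ± 0.373 FPKM (SD, n = 3), Aspn, asporin, from 6.12 ± 1.08 to 0.149 ± 0.0445 and Prelp from 207 ± 20.8 to 103 ± 1.73, whereas Ogn rose by a log2 fold change of 3.58. Camera gave the list an unadjusted p of 0.000546, and 0.146 with an estimated correlation. Of 12 secreted BMP and activin antagonists, 2 rose and 8 fell, Grem1 and Fst among them, while Chrdl1 rose from 0.0491 ± 0.00744 to 5.88 ± 0.245 (list p = 0.0444 by camera, and p = 0.161 with an estimated correlation).

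Type I keratin genes, which lie side by side on chromosome 11, moved in both directions. Krt13 rose from 2.33 ± 0.121 to 9.83 ± 0.338 FPKM (SD, n = 3), and Krt36, Krt19 and Krt15 rose by between 1.43 and 1.65 on the log2 scale, while Krt14 fell by 3.25 and Krt16 by 1.11. Camera gave this list an unadjusted p of 0.0805, and 0.146 with an estimated correlation. Among the D-type cyclins and their kinases, Ccnd1 fell from 14.2 ± 0.196 to 6.71 ± 0.319 FPKM, Cdk4 fell by a log2 fold change of 0.23 and Ccnd2 rose by 0.35 (list p = 0.544 by camera, and p = 0.673 with an estimated correlation). Although the line is labelled endothelial, 1 of the 24 endothelial markers, Ecscr at 20.9, had a mean above 10 FPKM, against 13 of the 17 mesenchymal transition genes; the other endothelial markers were lower or are not analysed here.

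Alpl rose while the osteocalcin genes and Runx2 fell. The tables argue against reads exchanged among the osteocalcin copies, since the summed FPKM of Bglap, Bglap2 and Bglap3 was lower by at least 2.66 on the log2 scale in every pair of libraries. Osteoblasts mixed into the treated cultures stay open as the cause of the rise of Alpl: of the 4 abundant osteoblast genes outside the pattern, 2 rose, Col1a1 and Spp1, while Col1a2 (log2 fold change 0.0031) and Sparc (-0.14) did not pass the test, which decides neither way. The summed osteocalcin genes fell from 36.5 to 4.56 FPKM and Runx2 from 6.56 to 3.65. As these are osteoblast genes, their falls argue against such a mixture as the whole cause of the pattern. An effect of the retinoid on the cells themselves is open too.

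Across the 27 tested Hox genes, the log2 fold change fell with paralog number (Spearman's rho -0.72, permutation p = 5e-05; Pearson's r -0.68), where genes of a cluster are not independent replicates. Of the 11 genes of paralogs 1 to 5, 10 rose, with a median of 0.81; of the 16 of paralogs 6 to 13, 8 rose and 3 fell, with a median of 0.24. Expression level is argued against by random sets matched on mean FPKM, of which 0% of 10000 had as high a median, and a pseudocount effect by a rho of -0.74 with a pseudocount of 0.1. Without the genes that overlap another listed gene on their strand the rho was -0.71 over 18 genes (permutation p = 0.0015), which argues against shared reads as the whole cause. A response graded along the clusters may be present, as a hypothesis found and tested on the same libraries.

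Log2 fold changes of neighbouring genes were weakly correlated, with Spearman's rho of 0.148 over 11541 pairs against at most 0.0304 in 1000 shuffled orders, where genes are not independent replicates. The rho was 0.153 without pairs whose loci overlap and 0.134 without pairs of the same symbol stem, which argues against each of these as the whole cause. A trend on transcript GC content explained 0.00207 of the variance of ranked log2 fold changes, the highest rho that it alone could give, which argues against it as the whole cause too. A regional component of the response may be present, but other regional properties were not tested.

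The 6 libraries allow 10 splits into groups of 3, too few for a share under 0.05. Each other split mixes both treatments within its groups, so the treatment difference enters the spread within groups and holds calls of genes and transcripts down. The contrast in these calls therefore does not measure chance, and no conclusion is drawn from it. The real split, as the 1 split with a count as large, gave 4976 changed genes against at most 3 in the others, 2217 higher against 3, 2759 lower against 3, 432 changed at least 2-fold against 3, and 2724 changed transcripts against 31. The real split gave 6 gene lists past camera, and 2 of the 10 splits gave as many, itself included. The other splits gave between 1 and 6. Calls of lists were not held down in the same way: 1 other split gave 6 lists with 0 genes changed. The number of lists called at the preset correlation therefore does not by itself set the real split apart.

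Among the 11584 tested genes, 5 were listed at 0 in a library while another library of their group was at 5 FPKM or more: Eif3j2, Gm20431, Gm28051, Hist2h2aa1 and Map2k7. Of these, 3 overlap another listed gene on the same strand, against 3.71% of all tested genes, and 0 passed limma's test.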
